A study of Mus musculus with 8 samples.

How the data were processed

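RNA was measured in GFP-positive and GFP-negative cells sorted from mouse limb buds at E13.5, midgestation. Per the labels' protocols, the buds were dissociated with collagenase and neutral protease, sorted by fluorescence, and total RNA was made into stranded poly(A)-selected libraries. The 8 libraries form 4 groups of 2: wild-type (WT) GFP-positive, WT GFP-negative, Y440X GFP-positive and Y440X GFP-negative. In each group replicate 1 is forelimb and replicate 2 is hindlimb, which the design text counts as biological replicates. Each library holds pooled buds of several fetuses, and the GFP-positive and GFP-negative libraries of a limb were sorted from suspensions of pooled buds, so pool-level differences are shared between fractions. Adjusted p-values of single genes below measure the spread between 1 forelimb and 1 hindlimb library per group, so they mix limb difference with other variation. Hypergeometric and Fisher's exact p-values below count genes instead. They hold no spread between libraries and treat genes as independent of each other, which genes measured in the same libraries are not.

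The submitters' processing notes name featureCounts, edgeR 3.36.0 and the builds GRCm38 and mm10, without a role or an order. The aligner is not given in the sources used here. The deposited tables also give a gene length in bases, a unit of its own kind (other), per the file headers. They list genes called by the authors as higher or lower in Y440X, 1 pair of tables per fraction. The authors' comparison columns hold a log2 fold change of Y440X over WT, a log2 average of CPM, counts per 1e+06 reads (logCPM), an F statistic, which is a score of their quasi-likelihood test, a p-value and its false discovery rate (FDR), per the file headers. Every listed gene had an FDR under 0.05 and an absolute log2 fold change of at least 1 in the authors' deposited table.

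The per-library columns are called RPKM in the file headers, but the deposited values are read counts. They were whole numbers in 100% of cells. Divided by the authors' CPM they gave nearly 1 library size for 316 genes with at least 200 counts, whatever the gene length, with a median of 44.4 and a 5th to 95th percentile of 41.5 to 46.8 in units of 1e+06 reads. Read as RPKM, they would have implied CPM off from the authors' by a median factor of 167. The planned test assumed RPKM, so edgeR's quasi-likelihood test on counts replaced it as the main test and limma on log2(RPKM + 1) became an alternative. RPKM for that alternative and for the filters were computed from the counts, the library sizes below and the deposited gene length.

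Only the 739 distinct listed genes are in hand, so column totals are not depth. Effective library sizes (after the authors' scaling) were solved by least squares from the deposited logCPM and log2 fold changes of genes with at least 200 counts. The solution returned the deposited log2 fold changes with a median absolute residual of 0.00025 and a largest one of 0.0023. The sizes were 38594000 and 42735000 reads for WT GFP-positive replicates 1 and 2, and 45615000 and 44968000 for Y440X GFP-positive. They were 46840000 and 44313000 for WT GFP-negative, and 50749000 and 47825000 for Y440X GFP-negative. There were 0 sample columns left unused. CPM below are counts over these sizes, per 1e+06 reads, so a gene at 1 CPM rests on 38.6 to 50.7 reads in a library. Bounds given for genes with 0 counts cover counting error only.

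The number of genes the authors tested was found from the FDR and p-value of the first gene of each fraction, which together bound it to between 16223 and 16265 (16244 was used). By the same arithmetic about 1567 genes in GFP-positive and 2671 in GFP-negative cells had an FDR at or under that of the last listed gene. The lists are thus the 2-fold subset, 19.3% and 19.1% of these. Genes outside the lists were not analysed here.

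edgeR 4.0.16 was run in R 4.3.3 with its quasi-likelihood test as in version 3, on all 739 genes, each fraction alone (2 libraries against 2), with the effective sizes and no further scaling. Standard errors are Wald errors from the fitted weights and the posterior quasi-dispersion. P-values were adjusted by Benjamini-Hochberg over the genes listed for the fraction. These genes were selected by the authors on the same libraries, so passing again is not independent evidence, and the adjusted p-values are smaller than the authors' FDR over all tested genes. Genes of 1 fraction were also tested in the libraries of the other fraction, whose own difference between genotypes was not what chose them. The deposited logCPM averaged all 8 libraries (median absolute residual 0.0025). The other fraction may therefore have entered the authors' filter and spread estimates. This was repeated without the 74 genes listed in both, which removes genes for their result in the libraries tested. A fraction by genotype interaction was fitted on all 8 libraries, adjusted over the 739 genes. Tests were two-sided unless stated. An exact permutation test of 2 libraries against 2 cannot give a p under 0.333. On simulated data with the real means and sizes of the GFP-positive libraries (739 genes) the edgeR step recovered 59.3% of 91 genes changed 2-fold and 91.7% of 109 genes changed 4-fold, and called 0.928% of 539 unchanged genes. For the GFP-negative libraries it recovered 65.2% of 89 and 97.3% of 111, and called 1.67% of 539. The simulated genes were independent of each other. Their spread followed a trend fitted to these selected genes, with none of their own, so the rates may be better than on real data.

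Before the data were examined, 22 gene lists were fixed: cartilage matrix, chondrogenic regulators, hypertrophy and bone, hedgehog, Wnt, BMP and TGF-beta, FGF, joint interzone, tendon, dermal and connective fibroblast, skeletal muscle, limb patterning, epithelium, erythroid, endothelium, macrophage and leukocyte, Schwann and neural, hypoxia and glycolysis, immediate early and heat shock, ER stress, cell cycle, and a sex-linked check. Fisher's exact test compared the direction of listed members with that of the other listed genes, for lists with at least 3 listed members, adjusted over those lists. A one-sided hypergeometric test, added after the data were seen, compared the number of listed members with the number due by chance among 16244 genes. It counted every member as tested, which lowers the excess, and was adjusted over the 22 lists.

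Genes were named by a rule fixed in advance: Sox9, the 8 largest higher and 8 largest lower differences of mean log2(RPKM + 1) per fraction, up to 4 members with the largest difference from each list, and up to 10 genes listed in both fractions. The 8 largest excluded predicted genes, pseudogenes, genes under a mean RPKM of 1 in the higher group and genes whose limbs differed in sign. Col2a1, Acan, Wnt9b and Csf1r in GFP-positive cells, the examples of genes listed in both fractions other than the 10, and the genes of the closing section's observations (chemokine ligands as every listed Ccl or Cxcl symbol with a number) were chosen after their values were seen. A bound for a gene with 0 counts in a group uses 3 counts over the group's libraries. The result of 1 gene that the rule named is not reported here. Coordinates are from GENCODE M21 (GRCm38), in which 717 of the 739 symbols were found.

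Alternatives were other pseudocounts, limma without a trend, centring on the other fraction's genes, an RPKM filter, limb as a block, and each library left out. Added after seeing the data were 1 fit of all 8 libraries, edgeR's version 4 method, DESeq2 1.42.0, TMM over the listed genes, library sizes from logCPM alone, the other fraction's genes without those listed in both, and the cell suspension as a block. limma was version 3.58.1. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 did the rest.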

Results

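Campomelic dysplasia is a skeletal malformation caused by mutations of SOX9, the transcription factor that directs cartilage formation. The study compared fetal mice carrying 1 Sox9 allele with the Y440X mutation and an IRES-EGFP reporter (Y440X) with mice carrying the reporter on an otherwise normal allele (WT). GFP-positive cells are those transcribing the tagged Sox9 allele, and GFP-negative cells are the rest of the limb bud. There were 8 RNA-seq libraries at E13.5: 2 genotypes, 2 sorted fractions, and forelimb and hindlimb as the 2 replicates of a group. Effective library sizes lay between 38594000 and 50749000 reads. The listed genes, the only ones in hand, took 8.34% and 6.03% of the WT GFP-positive libraries and 2.97% and 2.52% of the Y440X ones. In the GFP-negative libraries they took 1.40% and 1.27% of WT and 0.841% and 0.812% of Y440X. Values are mean CPM ± SD (n = 2), and log2 fold changes are Y440X over WT ± SE from edgeR.

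Sox9 itself (chromosome 11, 112782224 to 112787760, plus strand, GRCm38) was measured first, from both alleles together. In GFP-positive cells it was at 1070 CPM in forelimb and 922 CPM in hindlimb of WT, and at 474 and 558 CPM of Y440X. In GFP-negative cells it was at 97.2 and 72.3 CPM of WT, and at 18.0 and 22.0 CPM of Y440X. The log2 fold change was -2.09 ± 0.19 in GFP-negative cells, where the authors' deposited table lists Sox9 with an FDR of 0.0015. In GFP-positive cells, where it is not listed, it was -0.95 ± 0.28 (edgeR adjusted p = 0.013 over the 510 genes listed for the other fraction, 0.031 without those listed in both). The call over the 510 was lost when any of the 4 libraries was left out, with adjusted p between 0.0651 and 0.201 and log2 fold changes between -1.07 and -0.83, and under TMM scaling over the listed genes (-0.27). The fold change differed between fractions by 1.14 on the log2 scale (interaction, edgeR adjusted p = 0.012). Because the sort used a reporter inside Sox9, the gate itself selects on Sox9 expression.

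**Figure D1:**
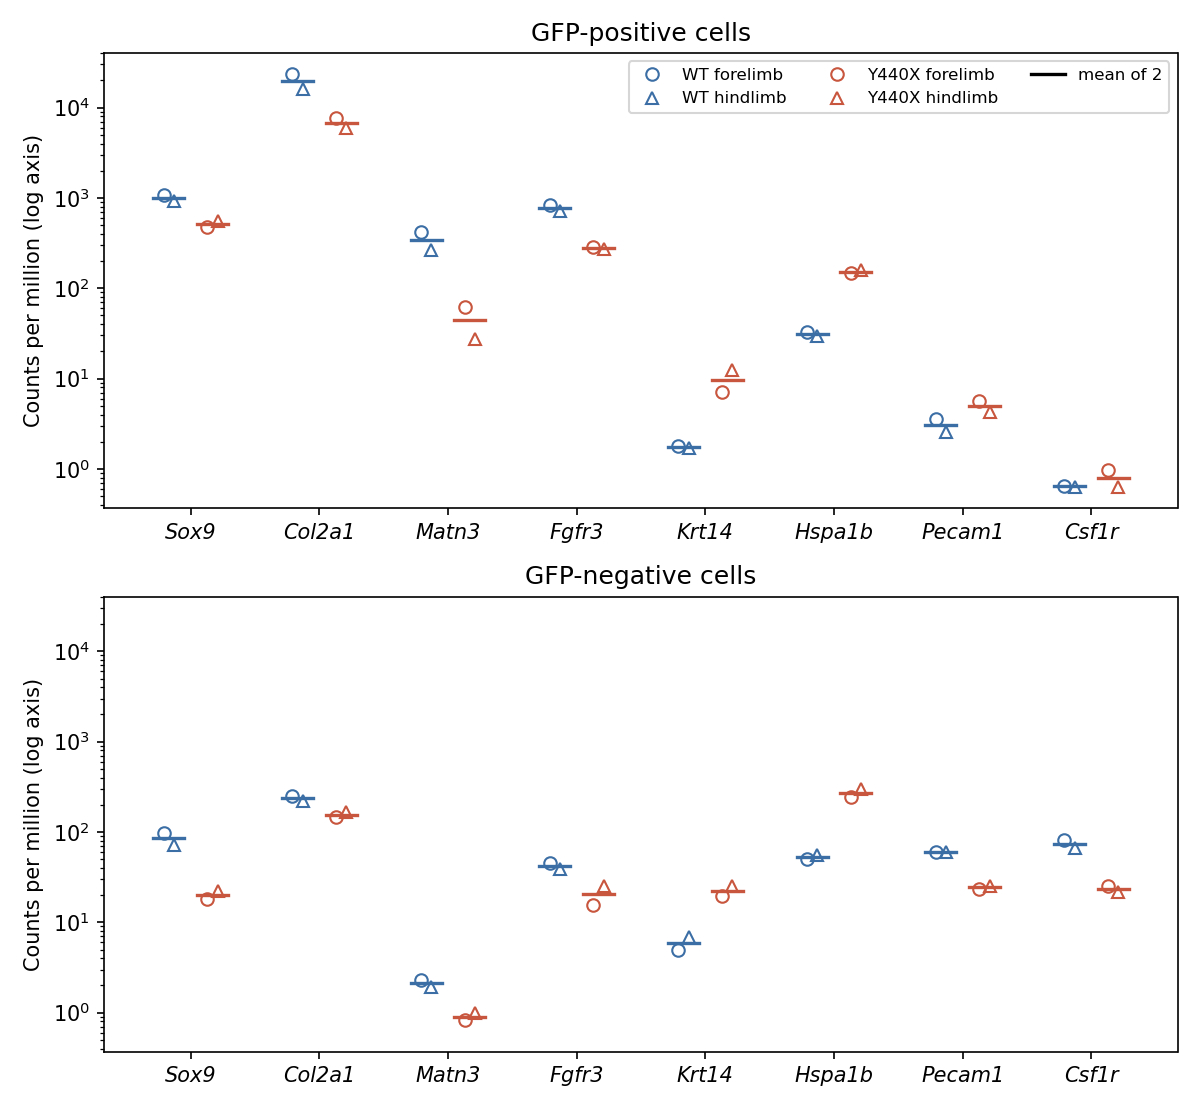
CPM on a log axis for 8 genes in each of the 8 libraries, GFP-positive cells above and GFP-negative cells below, with circles for forelimb, triangles for hindlimb and bars for the mean of 2. The means of Sox9, Col2a1, Matn3 and Fgfr3 were lower in Y440X in both fractions and those of Krt14 and Hspa1b higher. Those of Pecam1 and Csf1r were lower in GFP-negative cells and higher in GFP-positive cells. Csf1r in GFP-positive cells rests on 25 and 27 reads in WT and 44 and 28 in Y440X, with no rise in hindlimb CPM. Fgfr3 and Col2a1 in GFP-negative cells measured 0.04 and 0.47 under TMM scaling over the listed genes.

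The first comparison asked which listed genes differed between genotypes in the GFP-positive sort. In GFP-positive cells, cartilage genes were lower in Y440X, and genes of the surface epithelium and heat shock genes were higher. The authors' tables list 303 genes, 76 higher and 227 lower. Genes of the cartilage matrix made the largest fixed group: 18 of the list's 30 members were listed and all 18 were lower, with a median log2 fold change of -1.78. Type II collagen Col2a1 (chromosome 15, 97975602 to 98004695), the main cartilage collagen, went from 19827 ± 5504 CPM in WT to 6834 ± 1303 CPM in Y440X. Matn3, a matrilin of growth cartilage, went from 340.5 ± 106 to 44.4 ± 23.7 CPM (log2 fold change -2.94 ± 0.32). Hapln1, which links aggrecan to hyaluronan, went from 1894 ± 492 to 361 ± 86.2 CPM. Lect1 (chondromodulin) and Chad (chondroadherin) had log2 fold changes of -2.26 ± 0.32 and -2.39 ± 0.25. Aggrecan, Acan, is not listed for this fraction and measured -2.01 ± 0.35. Chance gives 0.56 listed members for a list of this size (hypergeometric adjusted p = 7.0e-23; Fisher's exact test of direction, adjusted p = 0.031). In this fraction every listed member of every fixed list passed edgeR both over the 303 genes and adjusted over the list alone, but they were selected on these libraries, so neither is independent evidence.

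Regulators of cartilage formation were lower with it. The transcription factors Foxa3, Sox8 and Sox5 had log2 fold changes of -4.03 ± 0.29, -2.0 ± 0.24 and -1.16 ± 0.27, and the growth factor receptor Fgfr3 -1.47 ± 0.27. These 4 are the listed members of 25 (hypergeometric adjusted p = 0.004). Of the hypertrophy and bone list, Ihh, the hedgehog ligand of prehypertrophic chondrocytes, went from 110 ± 15.3 to 28.2 ± 10.7 CPM. Panx3 and Phospho1 were also lower (-1.11 ± 0.24 and -1.71 ± 0.35), and Alpl, the bone alkaline phosphatase, was higher (1.31 ± 0.26). These 4 were more than chance gives (hypergeometric adjusted p = 0.0025). Ihh was also the 1 listed member of the hedgehog list. Nog, a BMP antagonist, fell by 1.83 ± 0.25 on the log2 scale and was the 1 listed member of the BMP and TGF-beta list. Fgfr3 was the 1 listed member of the FGF list.

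Markers of nerve-associated Schwann cells and of muscle were also among the lower genes. Erbb3, Sox10, Fabp7 and Cdh19, all expressed by Schwann cells or their precursors, had log2 fold changes of -1.90 ± 0.26, -1.75 ± 0.24, -1.90 ± 0.38 and -1.29 ± 0.28 (4 of 23 members, hypergeometric adjusted p = 0.0035). The muscle genes Casq2, Myh7 and Cacna1s were listed as lower, but at 0.547, 0.556 and 0.28 CPM in WT (3 of 38, hypergeometric adjusted p = 0.082). Myh7 lost its call without WT GFP-positive replicate 1 (log2 fold change -1.35) and in limma on log2(RPKM + 1), and Cdh19 under TMM scaling over the listed genes (-0.61).

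Among the higher genes, epithelial genes stood out by direction. All 9 listed epithelial genes were higher (of 24 members, median 1.67; Fisher's exact test of direction, adjusted p = 2.2e-05). The basal keratins Krt14 and Krt5 had log2 fold changes of 2.47 ± 0.29 and 2.29 ± 0.29; Krt14 went from 1.76 ± 0.0746 to 9.76 ± 3.66 CPM. The adhesion genes Epcam and Dsp had log2 fold changes of 1.39 ± 0.24 and 1.67 ± 0.28. In WT, Krt14 had 70 and 73 reads in GFP-positive and 234 and 307 in GFP-negative libraries. Krt5 had 131 and 142 against 555 and 511. Whether the keratin rises lie in Sox9-expressing cells or in other cells within the sort was not tested. Of the Wnt list 5 genes were higher and 2 lower (Fisher's exact adjusted p = 0.031). The ligands Wnt6 and Wnt3 had log2 fold changes of 3.05 ± 0.41 and 3.03 ± 0.60, both from under 0.3 CPM in WT. The receptor Fzd9 and the Wnt effector Lef1 were lower (-2.26 ± 0.29 and -1.05 ± 0.25). Wnt9b had 0 counts in WT and 26 in Y440X, at least 7.78-fold higher. The median of the 7 Wnt genes, 2.15, was the same with Wnt9b at that bound. Wnt7a stands in both the epithelial and the Wnt lists.

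The heat shock genes Hspa1b, Hspa1a and Hspb1 were also higher, at 2.29 ± 0.24, 2.31 ± 0.24 and 2.16 ± 0.25 (Fisher's exact adjusted p = 0.031). Hspa1a and Hspa1b are near-identical copies, whose reads cannot be told apart reliably. Hspa1b rose by a like amount in GFP-negative cells (2.36), so its rise is not particular to GFP-positive cells. Pool and genotype are confounded, so a difference between pools cannot be told apart from an effect of genotype. Meox1, a mesoderm homeobox gene, and Adamtsl2, a secreted matrix protein, measured 1.98 ± 0.25 and 1.39 ± 0.24. Of the largest decreases, Eno1b went from 40.4 ± 0.0835 to 0.232 ± 0.112 CPM. Its sequence is close to that of Eno1, so its counts are uncertain. Mir703, Mfi2 and Fxyd3 had log2 fold changes of -2.89 ± 0.26, -3.35 ± 0.26 and -3.39 ± 0.33.

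Direction was tested for 8 lists, and the 4 without a call (chondrogenic regulators, hypertrophy and bone, muscle, and Schwann and neural) had adjusted p between 0.658 and 1. By number of listed genes 8 of the 22 lists passed the hypergeometric test. Crabp1 was higher (1.01 ± 0.26, dermal and connective fibroblast), as were Cdkn2b (1.32 ± 0.36, cell cycle) and Robo4 (1.27 ± 0.36, endothelium). Cyp26b1 (limb patterning) and Laptm5 (macrophage and leukocyte) were lower at -1.17 ± 0.26 and -1.04 ± 0.26. The Y-linked genes Ddx3y and Uty were lower at -1.32 ± 0.24 and -1.01 ± 0.25. The joint interzone, tendon, erythroid, hypoxia and glycolysis, and ER stress lists had 0 listed genes. All 303 genes lay in 1 direction in both limbs without overlap, which 1 in 3 splits of 4 libraries gives by chance before selection. With the authors' FDR under 0.01, 102 genes were left, 14 higher and 88 lower. Among the 198 genes with a mean RPKM of at least 1, the cartilage direction test had an adjusted p of 0.394 with 19 of the 198 higher; too few Wnt genes were left for that test. Besides Sox9 and Cdh19, TMM scaling over the listed genes took the call from Lef1, Panx3, Laptm5 and Uty, and limma without the trend took it from Wnt3, Cacna1s and Myh7.

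**Figure D2:**
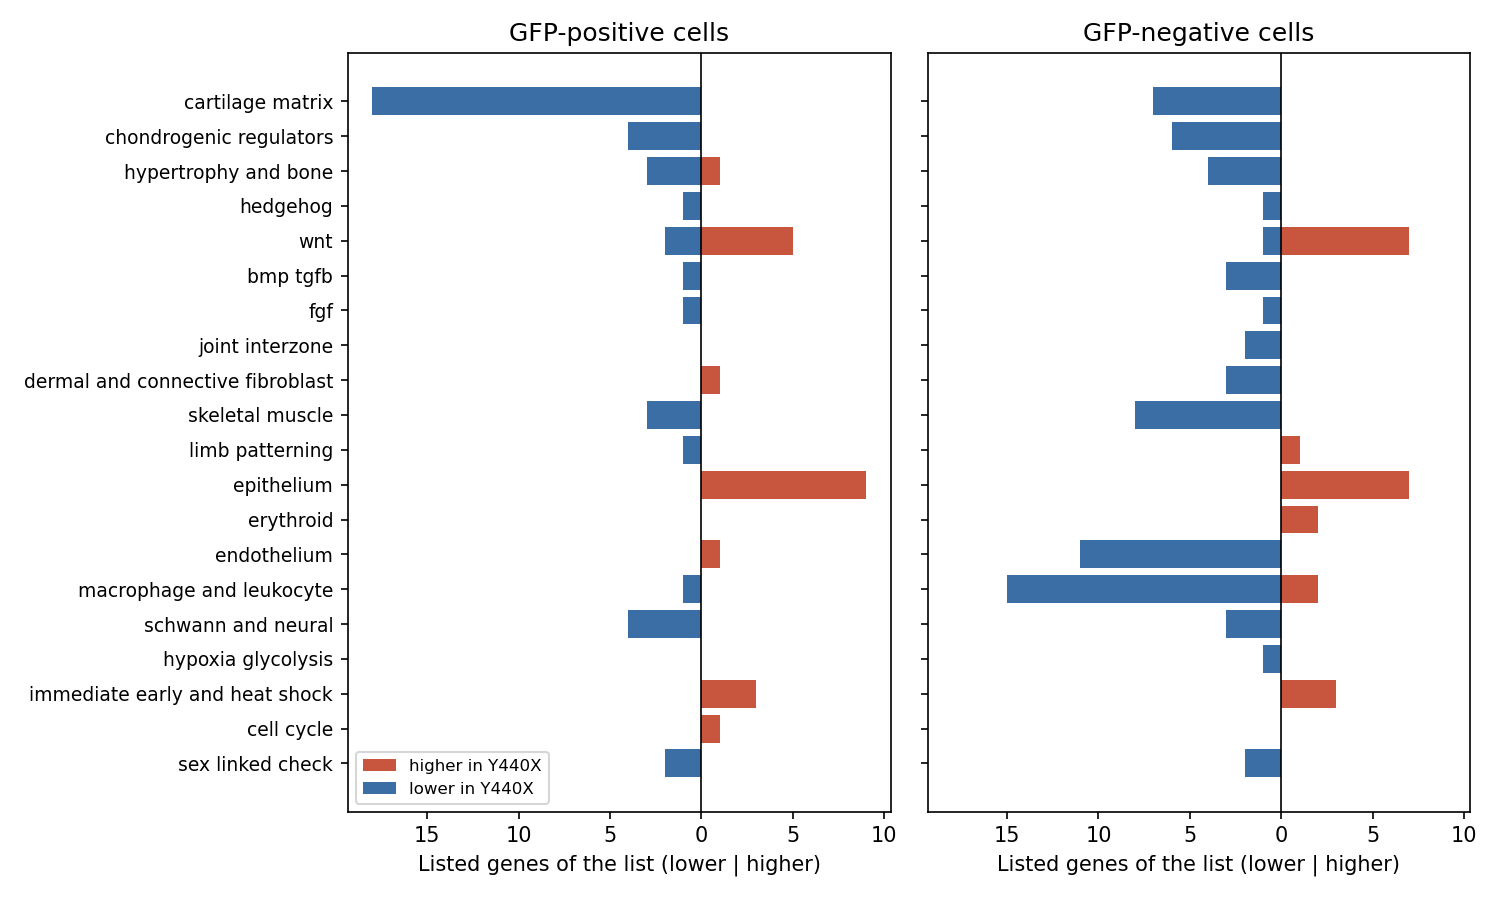
Number of listed genes of each fixed list, bars to the right for genes higher and to the left for genes lower in Y440X, GFP-positive cells on the left and GFP-negative cells on the right. Cartilage matrix has 18 lower genes in GFP-positive cells, and the macrophage and leukocyte list has 15 lower and 2 higher in GFP-negative cells.

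The second comparison asked the same of the cells outside the reporter gate. In GFP-negative cells, most listed genes of macrophages, blood vessels, muscle and cartilage were lower in Y440X, and epithelial genes were higher. The authors' tables list 510 genes, 85 higher and 425 lower. With most listed genes lower, the direction test made no call for these 4 lists (Fisher's exact adjusted p = 1, 0.675, 0.872 and 1). Of the 25 macrophage and leukocyte genes 17 were listed, 15 lower and 2 higher (hypergeometric adjusted p = 4.1e-19). The mannose receptor Mrc1 went from 148 ± 8.92 to 26.1 ± 4.62 CPM, and Pf4 from 16.3 ± 1.89 to 3.48 ± 0.098 CPM. The 2 higher members, S100a8 and S100a9, encode the calprotectin of neutrophils and had log2 fold changes of 3.12 ± 0.30 and 3.49 ± 0.30. The chemokine genes Cxcl2 and Ccl4 and the scavenger receptor Cd36 were among the largest decreases, at -3.55 ± 0.38, -2.46 ± 0.24 and -2.98 ± 0.22.

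Of the 21 endothelial genes 11 were listed and all 11 were lower (median -1.28, hypergeometric adjusted p = 7.7e-11). The junction protein Pecam1 went from 60.7 ± 0.0664 to 24.5 ± 1.41 CPM. Lyve1, also expressed by fetal macrophages, went from 15.7 ± 2.81 to 1.55 ± 0.652 CPM. Sox7 and Cldn5 had log2 fold changes of -2.06 ± 0.22 and -1.28 ± 0.22. Of 38 skeletal muscle genes 8 were listed and all 8 were lower (median -1.36, hypergeometric adjusted p = 0.0001), of which Actn2 lay above 0 under TMM scaling over the listed genes. They include the contractile genes Mylpf, Tnnc1, Tnnc2 and Acta1, at -1.18 ± 0.18, -1.09 ± 0.18, -1.46 ± 0.28 and -1.36 ± 0.20.

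Listed cartilage genes were lower here too, at far lower levels. In WT, Matn1 had 170 and 97 reads here against 48843 and 35382 in GFP-positive libraries. Hapln1 had 892 and 664 against 86542 and 66082. Whether such reads come from GFP-negative cells or from GFP-positive cells carried into this sort was not tested. All 7 listed members were lower (hypergeometric adjusted p = 0.00014). Of the 20 members with counts 19 lay below 0 (median -0.95), and 9 of the 20 under TMM scaling over the listed genes (median 0.13). Acan went from 12.6 ± 8.39 to 1.40 ± 1.003 CPM and Mia from 2.07 ± 0.601 to 0.233 ± 0.0333 CPM. Col9a3 and Cytl1 measured -1.20 ± 0.18 and -2.05 ± 0.32. All 6 listed regulators, Sox9 included, were lower, with Fgfr3 at 0.04 under TMM scaling over the listed genes (hypergeometric adjusted p = 0.00036). They include Foxc1 (-2.68 ± 0.34), Mef2c (-1.08 ± 0.18) and Fgfr3 (-1.05 ± 0.24), which was also the 1 listed gene of the FGF list. All 4 listed hypertrophy and bone genes were lower: Spp1, Mmp13, Alpl and Panx3 measured -2.26 ± 0.32, -2.17 ± 0.40, -1.26 ± 0.25 and -2.09 ± 0.59 (hypergeometric adjusted p = 0.0086). The joint genes Gdf5 and Prg4 measured -1.20 ± 0.19 and -1.75 ± 0.32. Gdf5, Nog and the receptor Bmpr1b were the 3 listed BMP and TGF-beta genes, the last 2 at -1.08 ± 0.17 and -1.27 ± 0.21 (hypergeometric adjusted p = 0.17). The Schwann and neural genes Ednrb, Foxd3 and Cdh19 measured -2.04 ± 0.36, -2.42 ± 0.43 and -2.07 ± 0.34 (hypergeometric adjusted p = 0.075). Of the 6 members of that list with counts 5 lay below 0 and 1, Erbb3, above. The fibroblast transcription factors Ebf1, Ebf2 and Ebf3 measured -1.07 ± 0.18, -1.08 ± 0.21 and -1.10 ± 0.17, with Ebf1 at 0.00025 under TMM scaling over the listed genes (hypergeometric adjusted p = 0.086).

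All 7 listed epithelial genes were higher (Fisher's exact adjusted p = 3.5e-05). Krt14 went from 5.96 ± 1.37 to 22.3 ± 3.82 CPM and Krt5 from 11.7 ± 0.224 to 36.7 ± 6.12 CPM. Dsp and Krt17 measured 1.49 ± 0.19 and 1.37 ± 0.26. Of 8 listed Wnt genes 7 were higher (Fisher's exact adjusted p = 0.00012). Rspo1, a Wnt agonist, went from 7.60 ± 0.121 to 22.8 ± 9.82 CPM. Wnt6 and Wnt7b measured 1.84 ± 0.34 and 2.34 ± 0.43, and the 1 lower member, the receptor Fzd4, -1.22 ± 0.15. Among the 281 genes with a mean RPKM of at least 1 the Wnt direction test had an adjusted p of 0.117. Alas2, an enzyme of heme synthesis in red cell precursors, measured 1.83 ± 0.17. The heat shock genes Hspa1b, Hspa1a and Hspb1 were higher at 2.36 ± 0.15, 2.19 ± 0.18 and 1.06 ± 0.27 (Fisher's exact adjusted p = 0.018; hypergeometric adjusted p = 0.0848). Stfa1 and BC100530, members of a multigene family whose reads cannot be told apart reliably, measured 2.73 ± 0.34 and 3.56 ± 0.46.

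In the remaining lists Meis1 was higher (1.32 ± 0.29, limb patterning), and Dhh (-1.54 ± 0.40, hedgehog) and Adm (-1.02 ± 0.28, hypoxia and glycolysis) were lower, with Adm at 0.05 under TMM scaling over the listed genes. Adm lost its call without WT GFP-negative replicate 1 (-0.78, adjusted p = 0.0546). Ddx3y and Uty were lower at -1.88 ± 0.15 and -1.32 ± 0.21. The tendon, ER stress and cell cycle lists had 0 listed genes. Direction was tested for 12 lists, and the 9 without a call (the 4 above, chondrogenic regulators, hypertrophy and bone, BMP and TGF-beta, fibroblast, and Schwann and neural) had adjusted p between 0.675 and 1. By number of listed genes 9 of the 22 lists passed the hypergeometric test. All 510 genes passed edgeR, and every list member also adjusted over the list alone, on the libraries that selected them. With the authors' FDR under 0.01, 177 genes were left, 21 higher and 156 lower. A mean RPKM of at least 1 in the higher group left 336 of the 510. Scaling by TMM over the listed genes alone, which were selected as changed, called 85 higher and 107 lower, 44.3% higher against 16.7% without it. It moved the median of all genes by 1.06 in GFP-negative and 0.67 in GFP-positive libraries, where it called 76 higher and 169 lower. In GFP-negative cells it took the call from 19 named genes: Acta1, Alpl, Bmpr1b, Cldn5, Col9a3, Dhh, Ebf2, Ebf3, Fzd4, Gdf5, Mef2c, Mylpf, Nog, Panx3, Pecam1, Prg4, Tnnc1, Tnnc2 and Uty. Panx3, Dhh and Mmp13 lost it in limma with libraries centred on the other fraction's genes, the first 2 also in limma without the trend.

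The third comparison asked which changes the fractions shared. Epithelial genes, heat shock genes and most listed Wnt genes were higher in both, and 5 cartilage matrix genes and several small non-coding RNAs were listed as lower in both. Of the 10 listed Wnt genes, Fzd9, Lef1 and Rspo1 (-0.0071) lay below 0 in GFP-positive cells, and Fzd4 and Fzd9 (-0.72) in GFP-negative cells. Of 74 genes listed in both fractions, 48 were lower in both, 19 higher in both and 7 higher in GFP-positive but lower in GFP-negative cells (Fisher's exact test of direction, p = 3.1e-12). Across all 739 listed genes, which were selected and are not independent of each other, the Spearman correlation of the log2 fold changes of the fractions was 0.087. Independent lists of these sizes would share 5.94, 0.398 and 1.99 genes. The 19 include Krt5, Krt14, Cdh1, Dsp, Grhl2, Wnt3, Wnt6, Wnt7a, Wnt9b and Rnf43. The 48 include Hapln1, Matn1, Col9a3, Cytl1, Susd5, Sox5, Fgfr3 and Nog. Whether the cartilage matrix genes fell in GFP-negative cells themselves was not tested, as said above. By size in both, the naming rule took Eno1b, Mir703, Hspa1b, Hspa1a, AA465934, Rmrp, Snord47, Snord72, Krt14 and Krt5. Rmrp, an RNA of a ribonuclease, measured -3.76 ± 0.67 and -3.22 ± 0.55 in GFP-positive and GFP-negative cells, from 1.09 and 0.963 CPM in WT. AA465934 measured -2.25 ± 0.26 and -2.85 ± 0.23. Snord47 and Snord72 lie within host genes, so their reads cannot be told apart from those of the hosts. Both fractions were sorted from the same pools, so the fractions are not independent of each other.

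Genes listed for 1 fraction were then measured in the libraries of the other, whose own difference between genotypes was not what chose that list. Those libraries may still have entered the authors' filter and spread estimates. Of the 227 genes listed as lower in GFP-positive cells, 183 were below 0 in GFP-negative libraries (median -0.56), and 91 passed edgeR as lower and 2 as higher. Of the 76 higher ones 47 were above 0 (median 0.26), with 25 passing as higher and 16 as lower. Of the 425 genes listed as lower in GFP-negative cells, 258 were below 0 in GFP-positive libraries (median -0.30), and 99 passed as lower and 24 as higher. Of the 85 higher ones 67 were above 0 (median 0.87), with 31 passing as higher and 3 as lower. These counts include the 74 genes listed in both. Without them 53 of 436 passed in GFP-positive and 39 of 229 in GFP-negative libraries. These are low counts by construction, since the 74 were removed for their result in the libraries tested. In GFP-negative libraries 135 of 179 lower ones were then below 0 (median -0.35), 32 passing as lower and 0 as higher. Of 50 higher ones 28 were above 0 (median 0.17), 4 passing as higher and 3 as lower. In GFP-positive libraries 210 of 370 lower ones were below 0 (median -0.15), 36 passing as lower and 7 as higher. Of 66 higher ones 48 were above 0 (median 0.64), 8 passing as higher and 2 as lower. The calls depended on the model. The 157 in GFP-positive libraries fell to 9 without WT replicate 1, 28 without WT replicate 2, 97 without Y440X replicate 2 and 95 in limma on log2(RPKM + 1), while the 134 in GFP-negative libraries were 128 in limma. With limb as a block edgeR called 199 in GFP-positive libraries, 158 in the listed direction and 41 in the opposite one, and 166 in GFP-negative libraries, 142 and 24. Without the block the opposite calls were 27 and 18. Under TMM scaling over the listed genes both lower groups turned, with medians of 0.50 in GFP-negative and 0.37 in GFP-positive libraries.

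The last comparison tested the difference between fractions itself. Endothelial genes were lower in GFP-negative cells while 11 of 12 lay above 0 in GFP-positive cells (median 0.70), or 9 of 12 (median 0.11) in the limma fit with libraries centred on the other fraction's genes. Macrophage and leukocyte genes had a median of 0.37 in GFP-positive cells and -0.00094 in that limma fit. In edgeR 10 of these 17 genes lay above 0 in GFP-positive cells and 6 below. Of 12 endothelial genes with counts, 11 passed the interaction test, all 11 with a higher log2 fold change in GFP-positive cells (median interaction 2.05). Of 17 macrophage and leukocyte genes 13 passed, 12 of them in that direction. Of the 12 endothelial genes, 11 are in hand because they were listed as lower in GFP-negative cells, and Robo4 as higher in GFP-positive cells. All 17 macrophage and leukocyte genes were listed for GFP-negative cells, 15 as lower. Selection thus favours this direction in both lists, and these counts are not independent support. Mmp13, Spp1, Alpl and Gdf5 also had higher log2 fold changes in GFP-positive cells, with interactions of 4.88, 2.58, 2.57 and 1.30. Mmp13 was under 0.2 CPM in GFP-positive cells. Of 20 cartilage matrix genes 12 passed, 11 of them with the larger fall in GFP-positive cells, such as Matn3 (-1.71) and Chad (-1.92). The exception was Mia (2.21). Of the 20, 18 were listed as lower in GFP-positive cells, which by itself favours a larger fall there. Mia and Acan, listed only for GFP-negative cells, both fell further in GFP-negative cells. Acan did not pass, and went from 870 and 297 to 107 and 33 reads there. In GFP-positive cells it went from 120516 and 86087 to 39087 and 18661. In all, 367 of 739 genes passed (edgeR, adjusted p under 0.05), 235 with a higher and 132 with a lower value in GFP-positive cells. Most genes are listed for 1 fraction and were selected for a large effect there, which inflates this count. Of the 74 listed for both fractions 13 passed.

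**Figure D3:**
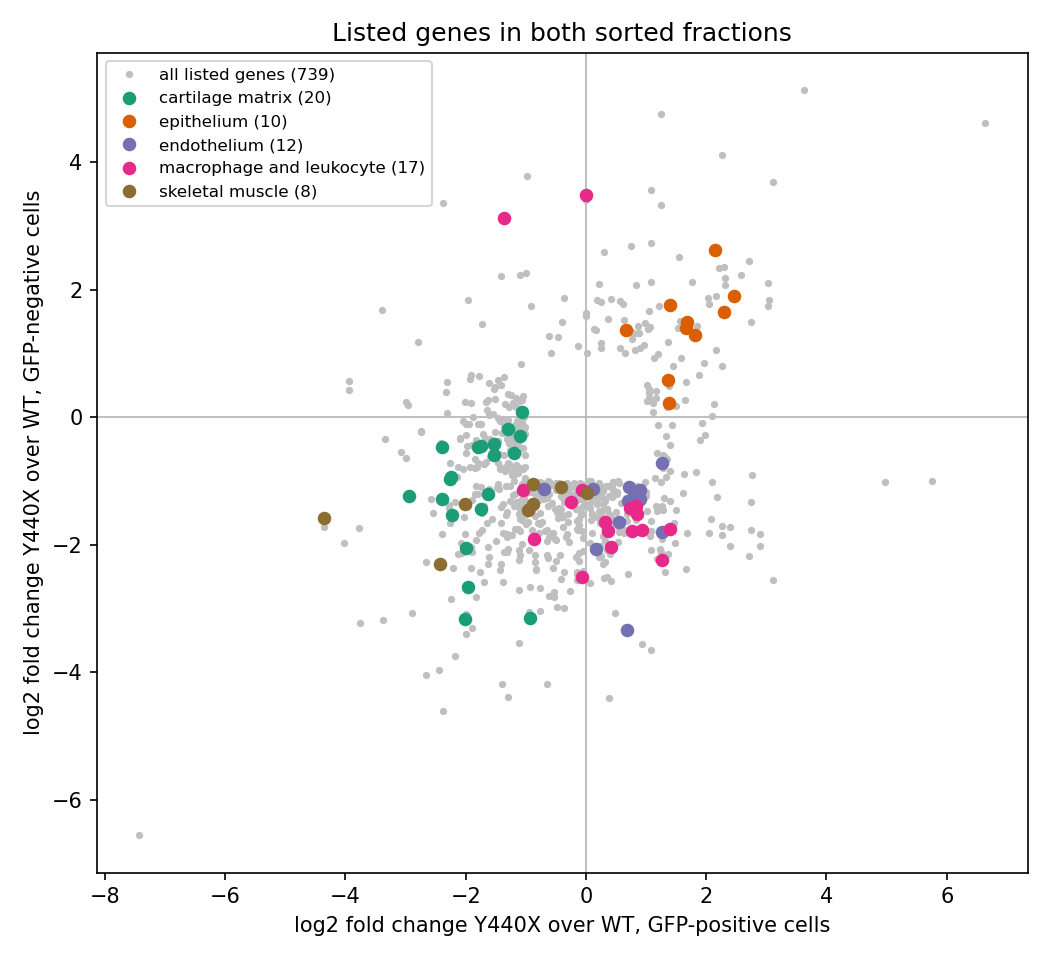
Log2 fold change of Y440X over WT in GFP-positive cells (horizontal) against GFP-negative cells (vertical), 1 point per listed gene, 739 genes, with 5 fixed lists coloured. Epithelial genes lie above 0 on both axes, and endothelial genes lie below 0 on the vertical and, in 11 of 12 cases, above 0 on the horizontal axis.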

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

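All tests of explanations in this part were chosen only after the results were seen. The genotype effect differed between fractions for 367 of 739 genes (interaction test), and among the genes named in the report or listed in opposite directions 52 had different effects in the 2 fractions. Differences are log2 fold change in GFP-positive minus that in GFP-negative cells.

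Most endothelial and macrophage genes were lower in GFP-negative Y440X cells. In GFP-positive cells 11 of 12 endothelial genes lay above 0. Of 17 macrophage and leukocyte genes only 10 lay above 0 there and 6 below (Laptm5 is listed as lower in both fractions). The differences were 2.0 for Pecam1, 2.18 for Cldn5, 2.23 for Sox7, 1.99 for Robo4, 4.02 for Lyve1, 2.44 for Mrc1, 3.50 for Pf4 and 2.63 for Cd36. Those of Lyve1 and Pf4 rest on few GFP-positive reads. Lyve1 had 15 and 11 in WT and 35 and 12 in Y440X, and Pf4 had 8 and 9, and 30 and 16. More GFP-negative cells of every kind in the Y440X GFP-positive sort stays open. The median difference of 12 endothelial genes exceeded that of 8 muscle genes, 2.05 against 0.33, by 1.72 (exact permutation over genes, p = 0.0038). This cannot decide, since equal carry-over gives equal differences only from equal starting ratios. In WT, Mylpf had 175 and 146 counts in GFP-positive and 1730 and 1691 in GFP-negative libraries. Pecam1 had 138 and 109 against 2839 and 2690. Macrophage genes were not compared in this test. Fewer endothelial cells in the whole suspension, with no other change, is argued against by a median of 0.70 in GFP-positive cells, where 11 of 12 endothelial genes lay above 0, against -1.28 in GFP-negative cells. In the limma fit with libraries centred on the other fraction's genes 9 of 12 lay above 0. The medians in that fit were 0.11 in GFP-positive and -0.85 in GFP-negative cells, with the lowest gene at -0.27 in GFP-positive cells. That fit adds 1 to the RPKM, which pulls changes of low genes towards 0. Before centring, Robo4 in GFP-positive cells measured 0.21 on that scale against 1.27 in edgeR. The size of a change in GFP-positive cells can thus not be read from that fit. A shift of endothelial and macrophage cells or their RNA across the sort gate, and a biological change of these cells with genotype, stay open and untested, since gate settings were not used here.

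The genes listed as higher in GFP-positive and lower in GFP-negative cells differed by 2.18 (Gimap6), 2.66 (Adgrl4), 2.70 (Rasgrp3), 3.17 (Fcrls), 2.25 (Bcl6b), 2.57 (Alpl) and 3.11 (Mfng). Sox9 differed by 1.14 and Foxc1 by 1.92. Cartilage genes differed by -1.71 (Matn3), -1.10 (Hapln1), -1.29 (Lect1), -1.92 (Chad) and 2.21 (Mia), and Sox8 by -1.44. Bone and joint genes differed by 4.88 (Mmp13), 2.58 (Spp1), -1.44 (Phospho1), 1.30 (Gdf5) and 2.17 (Prg4), and Nog by -0.75. Wnt list genes differed by -1.54 (Fzd9), -1.38 (Lef1), 1.43 (Fzd4) and -1.59 (Rspo1). Fibroblast factors differed by 1.01 (Ebf1), 1.45 (Ebf2) and 1.54 (Ebf3). Inflammatory genes differed by 4.49 (Cxcl2), 3.16 (Ccl4) and -4.49 (S100a8). Muscle genes differed by 1.19 (Mylpf) and -2.79 (Cacna1s), and Alas2 by -1.65. In GFP-positive cells S100a8 had 2 and 3 reads in WT and 0 and 2 in Y440X. Ccl4 had 5 and 1, and 5 and 6, and Cacna1s 9 and 14, and 1 and 0. The sizes of these 3 differences are thus uncertain. So are those of other genes with few reads in 1 fraction. In GFP-positive cells Mmp13 had 2 and 0 reads in WT and 9 and 7 in Y440X, and Mfng 4 and 7, and 22 and 31. In GFP-negative cells Fxyd3 had 7 and 3, and 12 and 23. Phospho1 had 13 and 16, and 13 and 13 there, and Cdkn2b 11 and 7, and 6 and 4. The remaining differences were 1.14 (Adamtsl2), 1.24 (Adm), 2.27 (Cdkn2b), -0.78 (Cyp26b1), 1.16 (Epcam), -2.13 (Erbb3), -5.07 (Fxyd3), 1.10 (Hspb1), 2.25 (Meox1) and -3.0 (Mfi2).

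The Y-linked genes Ddx3y and Uty were lower in Y440X in all 8 values (2 genes in 4 limb and fraction pairs), with log2 fold changes between -1.93 and -0.80. Fewer male fetuses in the Y440X pools may be the reason. It needs a fall that does not differ between fractions, and the lower of the 2 adjusted interaction p-values was 0.091, but 2 genes in pools whose sex is confounded with genotype cannot settle it. Xist, Eif2s3y and Kdm5d, the rest of the 5 genes of the sex-linked list, are listed for neither fraction. Fewer male fetuses would also lower the Y-linked Eif2s3y and Kdm5d, but how far they changed is not known here. Fewer male fetuses cannot be told apart from an effect of genotype on Ddx3y and Uty.

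RNAs that lack a poly(A) tail, or mostly do (small nucleolar, nuclear and micro RNAs, Rmrp, Rn45s and histone genes), were lower: of 19 such genes 15 are listed as lower in GFP-positive and 10 in GFP-negative cells, with Hist3h2ba the 1 listed as higher. A lower yield of such RNA in the Y440X libraries stays open: in the fraction that does not list them 91.7% (11 of 12) lay below 0, against 68.1% expected from other genes listed for the same fraction in the same direction (exact conditional test over genes, which are not independent of each other, p = 0.104). Their medians there were further below 0 than those of the other lower genes, -0.99 against -0.33 for genes listed for GFP-positive cells and -1.03 against -0.14 for genes listed for GFP-negative cells. The difference in size was not tested, and the 7 genes listed as lower in both fractions were left out here. Loss of short transcripts in general also stays open. The 153 shortest protein-coding genes lay 0.31 above the other 457 in median. They were not matched by the fraction and direction of listing, and reached 1893 bases in length, so this cannot decide. Reads of host genes and of precursors may enter these counts, and a biological change stays open.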

How the results depend on the processing

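The TMM, DESeq2, edgeR version 4, single-fit, logCPM-only and cell suspension alternatives and the fits without genes listed for both fractions were chosen after the data were seen; the others were planned. Of 129 summary values under alternatives 111 stayed within 1.5 times the reported count or on the same side of the threshold. Of 1675 values for 112 named results 1629 kept direction and call, 43 kept direction and lost the call (25 under TMM, the other 18 over other alternatives) and 3 reversed. TMM took the call from Sox9, Cdh19, Laptm5, Lef1, Panx3 and Uty in GFP-positive cells and from the 19 genes named in the report in GFP-negative cells. Of the 18, 4 were of Sox9 in GFP-positive cells, each with 1 library left out. Another 4 were of Myh7, and the rest of Cacna1s and Wnt3 in GFP-positive and Dhh, Panx3, Mmp13 and Adm in GFP-negative cells and of 2 list directions under the RPKM filter. Limb as a block left the counts of listed genes past edgeR at 303 and 510, and the interaction count ranged from 284 to 514 over its alternatives. All 303 and 510 genes passed without the block too, on the libraries that selected them, so those unchanged counts say little about stability. In the other fraction's libraries the block raised the number of calls, as given in the report. With 2 libraries per group, leaving 1 out assumes that the lone library varies like the other group.

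The authors' FDR under 0.01 left 102 listed genes in GFP-positive and 177 in GFP-negative cells, a stricter threshold by construction. A mean RPKM of at least 1 in the higher group left 336 in GFP-negative cells. Filtering on a mean RPKM of at least 1, which tests fewer genes, left 198 and 281 genes past edgeR, 2 lists with a direction in GFP-positive cells, and in the other fraction's libraries 120 and 94 genes (same sign, past the test) listed for GFP-negative and 137 of the same sign listed for GFP-positive cells. Of the genes listed for GFP-negative cells, those past the test in GFP-positive libraries numbered 95 with limma, 59 with limma without the trend, and 9 to 138 with 1 library left out; the cause was not tested. Without genes listed for both fractions 53 of 436 genes listed for GFP-negative and 39 of 229 listed for GFP-positive cells passed in the other fraction's libraries. Limma on log2(RPKM + 1) called 0 of either set and a limb block 116 and 75, while 0.1 and 0.5 as limma pseudocounts called 0 of the 436 and 26 and 16 of the 229. Genes were removed for their result in the libraries tested, which lowers these counts.

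TMM over the listed genes takes most of these genes as unchanged although they were selected for change. It gave 192 genes past edgeR in GFP-negative cells and 134 genes listed for GFP-positive cells with the same sign in GFP-negative libraries. It reversed Adm (0.054), Ebf1 (0.00025) and Fgfr3 (0.036) in GFP-negative cells, each near 0. Depth limits genes such as Rmrp, Wnt3, S100a8, Ccl4, Pf4, Lyve1 and the muscle genes listed for GFP-positive cells, at about 1 CPM or less in that fraction.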

Other observations

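The genes and tests in this part were chosen only after the values were seen. In GFP-negative cells Ltf (lactoferrin) and Ngp, genes of neutrophil granules, were higher in Y440X. Ltf went from 0.0552 ± 0.0177 to 2.01 ± 0.673 CPM and Ngp from 0.153 ± 0.025 to 2.16 ± 0.793 CPM (SD, n = 2). All 7 chemokine ligand genes listed for this fraction (Ccl3, Ccl4, Ccl9, Ccl12, Ccl24, Cxcl2 and Cxcl3) were lower, from -4.40 to -1.41 (median -2.46), as were 425 of all 510 listed genes. Cxcl12, listed as higher in GFP-positive cells (1.19 ± 0.25), measured -0.12 ± 0.13 in GFP-negative cells. Ccl3 went from 19.8 ± 2.06 to 3.997 ± 0.498 CPM, and the cytokine gene Tnf from 8.43 ± 3.87 to 1.795 ± 0.499 CPM.

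Eno1b (chromosome 18, 48045335 to 48048412) was nearly absent from all 4 Y440X libraries, at 0.232 ± 0.112 CPM in GFP-positive and 0.164 ± 0.0643 CPM in GFP-negative cells, against 40.4 ± 0.0835 and 15.5 ± 0.268 CPM in WT. Gt(ROSA)26Sor was lower in both fractions too, at -1.38 ± 0.24 and -1.81 ± 0.19. Their cause was not tested.

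A hypothesis that variants of another strain, carried along with the edited Sox9 allele, account for some listed genes was tested on neighbouring genes. Within 10 Mb of Sox9, 12 of 314 protein-coding genes were listed (3.82%), against 666 of 21636 elsewhere (3.08%), a ratio of 1.24 (Fisher's exact p = 0.41). The 95% log-normal interval of the ratio, 0.709 to 2.17, leaves both no excess and a moderate one open, so this test did not decide.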
